A study of Homo sapiens with 12 samples.

How the data were processed

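Total RNA of KM-H2tetPU.1 cells on days 0, 1 and 3 after tetracycline removal was measured on Illumina expression bead arrays, 4 per day and 12 in all. Per the labels, RNA was extracted with TRIzol and amplified and labelled with biotin. The signal table was deposited as linear probe intensity per array, which the authors exported with BeadStudio 3.3.7. Negative values and array medians near 0 show that background had been subtracted before it was deposited, with no scaling between arrays. Beside each signal stands a detection p-value, deposited by the authors per the file headers. The values of the series matrix as deposited by the authors are log2 signals less a constant per array, which lay within 0.000592 of log2 of the array's 75th percentile, and less the median of each probe over the arrays. These were used only as an alternative.

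Of 47231 probes, 3270 (6.92%) carry no identifier and were left out, although 766 of them were detected on at least 4 arrays. Background was corrected with neqc in limma 3.58.1 (R 4.3.3), which takes the background from the detection p-values and adds an offset of 16, followed by quantile normalization and log2. Probes with a detection p under 0.01 on at least 4 arrays were kept, 18670 in all. The name table gave 1 symbol to 14669 of these, and 4001 unnamed probes were tested but not assigned to a gene. A gene was represented by its kept probe with the highest mean, which gave 10916 genes, 2938 of them with 2 or more kept probes. The plots were drawn with Python 3.11.15 and matplotlib 3.10.9.

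Arrays were grouped by day as labelled. A limma model with 1 coefficient per day was fitted to all 12 arrays, and day 1 against day 0, day 3 against day 0 and day 3 against day 1 were tested with moderated statistics, two-sided, with Benjamini-Hochberg adjustment over all kept probes. A gene was called at an adjusted p under 0.05, and called changed at least 2-fold when its absolute log2 difference was also at least 1. The model, the thresholds, the 28 gene lists and the rule for naming genes were fixed before the data were examined. Lists with at least 5 measured genes were tested against all other genes by camera with a preset correlation of 0.01, adjusted over the 28 lists. All 28 were tested. SPI1 probes were also tested by a two-sided exact permutation test of 4 against 4 arrays, whose smallest possible p is 0.0286. A gene detected on all 4 arrays of 1 day and on none of the other has only a bound on its change, given as "at least N-fold". It was computed with each array of the dim day at the larger of the gene's own value and the lowest value of any detected probe on that array. A named gene detected on 1 to 3 arrays of the lower day has the same bound, with only its undetected arrays raised.

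By the naming rule, the 10 largest rises and falls on day 1 and on day 3 against day 0, and 5 and 5 for day 3 against day 1, were named among genes past the threshold, detected on at least 1 array of both days and without overlap between days. Up to 5 bounds per direction were added, with up to 4 members of each list, those with the smallest p in the direction of the list's median first, and 16 genes named in advance. Uncharacterised symbols were passed over. The rule named 388 gene and comparison pairs, of which 258 are reported. The other 130, all members of lists, were left out for length after their values were seen. TNFRSF8 and PAX5 of the 16 genes had no kept probe, and 1 other of them is not reported here.

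The correlation across genes of the day 1 and day 3 differences was set beside 100 simulations of unchanged groups with shared day 0 arrays, and beside splits of the day 0 arrays between the comparisons. Pairing by replicate number was checked by correlating, over probes, each array's deviation from the mean of its day. Arrays of the same number on different days correlated at 0.478 to 0.697, arrays of other numbers in the same set (replicates 1 and 2, or 3 and 4) at 0.498 to 0.658, and arrays of different sets at -0.659 to -0.458. Only 3 of 12 arrays correlated best with their own number on both other days, so the numbers follow the sets more than single pairs, and the replicate number as a block was run as an alternative.

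Alternatives fixed in advance were normexp with an offset of 50, no background correction, median centring, the series matrix values, no filter on dim probes, detection on all arrays of a day, trend and robust options, array weights, only the 8 arrays compared, the mean of the probes of a gene, the replicate block, leaving out each array in turn, camera with an estimated correlation, fry, treat against 1.2-fold and the splits of day 0. Blocking by slide was not run, because the files do not show slides. After the sets had been seen, 6 further alternatives were added: the set as a fixed block, the set within a day as a random block (without camera), arrays of a set averaged with and without the set as a block, and each set alone. Ranges of adjusted p given below over all alternatives leave out fry, which does not compare a list with other genes. They also leave out treat, which was run for counts only.

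The procedure was tested on simulated data with 200 changed genes of 10916 in the comparison of day 1 with day 0. With independent arrays it recovered 43.3% of 1.5-fold, 82.1% of 2-fold and 97.0% of 4-fold changes, with 5 false calls (3.27% of calls). With a set difference shared by all days it recovered 53.7%, 89.6% and 98.5%, with 1 false call. With the arrays of a set alike within each day, at a correlation of 0.6, it recovered 61.2%, 89.6% and 100% with 167 false calls (50% of calls), so the number of false calls depends on whether the arrays of a set are independent.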

Results

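The series profiled KM-H2tetPU.1, a derivative of the classical Hodgkin lymphoma line KM-H2 in which PU.1, the transcription factor encoded by SPI1, is switched on by taking tetracycline out of the medium. Total RNA from days 0, 1 and 3 was hybridised to Illumina expression bead arrays of 47231 probes. There were 4 arrays a day, 12 in all. The design text speaks of independent experiments but does not say whether these were separate cultures. So p-values here measure only the spread between these arrays, which may be technical. An array detected between 17808 and 19399 probes at a detection p under 0.01, and the 75th percentile of its signal lay between 91.9 and 134.1 intensity units. The number of arrays, 4 a day, limits the precision. Component 1 of a principal component analysis held 46.1% of the variance and placed the days in order, and component 3, with 16.8%, set day 1 apart from days 0 and 3. Component 2, with 24.4%, separated replicates 1 and 2 from replicates 3 and 4 on every day. The SD over genes of the log2 difference between 2 arrays of a day had a median of 0.233 within these sets and 0.423 between them.

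**Figure D1:**
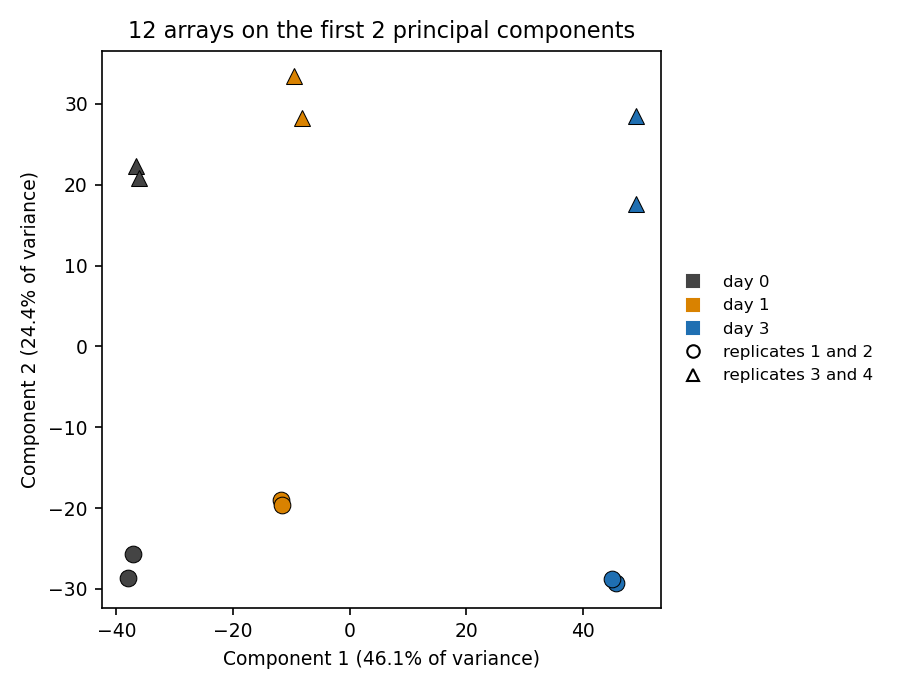
Each point is 1 array, placed by its scores on component 1 (x axis, 46.1% of variance) and component 2 (y axis, 24.4%). Colour gives the day and shape the set of replicates. On component 1 day 0 lies between -38.0 and -36.2, day 1 between -11.7 and -8.22 and day 3 between 45.1 and 49.1. On component 2 the sets lie on opposite sides of 0 on every day.

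The comparison of day 1 with day 0 asks which transcripts differ a day after tetracycline removal. PRG2, the major basic protein of eosinophil granules (probe ILMN_1729314), rose 111-fold, from a log2 intensity of 6.38 ± 0.27 (SD, n = 4) to 13.18 ± 0.07. This is a log2 difference of 6.79 ± 0.12 (SE, adjusted p = 5.58e-12). The zinc finger transcription factor EGR1 (ILMN_1762899), an immediate early gene, rose 11.5-fold from 7.38 ± 0.13 to 10.91 ± 0.21 (SD, n = 4; log2 difference 3.53 ± 0.12 SE, adjusted p = 1.72e-09). The dendritic cell nuclear protein gene DCANP1 (ILMN_1701911) and IL1RN, the interleukin-1 receptor antagonist (ILMN_1774874), were detected on no array of day 0 and on all 4 of day 1. They rose at least 29.5-fold and 12.4-fold. CCL1, a chemokine (ILMN_2086965), fell from 9.28 ± 0.16 to 7.17 ± 0.16 (SD, n = 4), a log2 difference of -2.11 ± 0.13 (SE, adjusted p = 2.88e-07).

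The other largest rises on day 1 were those of TCFL5, a helix-loop-helix transcription factor (log2 difference 3.51 ± 0.14 SE), ITIH1, a heavy chain of the inter-alpha-trypsin inhibitor (3.44 ± 0.12), and GPR84, a myeloid receptor for medium-chain fatty acids (3.32 ± 0.12). JAML, a leukocyte adhesion molecule, rose by 2.91 ± 0.12, and the aspartic protease gene NAPSA and its relative NAPSB by 2.83 ± 0.21 and 2.89 ± 0.22. The cadherin CDH11 rose by 2.77 ± 0.26 and the C-type lectin CLEC4A by 2.76 ± 0.10. Adjusted p for these 8 genes ran from 1.48e-05 down to 3.07e-09. MYBPC1, a myosin-binding protein, rose at least 18.8-fold, the receptor tyrosine kinase FGFR4 at least 12.9-fold and the interleukin-7 receptor chain IL7R at least 7.77-fold. Falls of 1.94 ± 0.10 to 1.58 ± 0.11 on the log2 scale were measured for LRIG1, SAMSN1, annexin A1 (ANXA1), the Notch target HEY1, macrophage elastase (MMP12), SNAP25, INHBE and the monocyte chemoattractant CCL2. Log2 differences were -1.94 for LRIG1, -1.82 for ANXA1 and -1.58 for CCL2. CCL2 lost its call without background correction (adjusted p = 0.0724) and with series matrix values (0.0576), over all alternatives 7.5e-08 to 0.0724. CYP4Z1, detected on all day 0 arrays and on none of day 1, fell at least 3.40-fold, and the BMP antagonist SOSTDC1, detected on 1 array of day 1, at least 2.66-fold. GDF15, SLFN11, TOX and the fucosyltransferase FUT9 fell at least 1.91-fold, 1.88-fold, 1.85-fold and 1.60-fold. None of the arrays of day 1 overlapped those of day 0 for any gene named so far, which the naming rule required of all but the bounds.

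Of 28 lists fixed in advance, the 1 with the smallest p on day 1 was the integrated stress response, genes of amino acid supply and of the ATF4 pathway. Of its 24 measured members 17 fell and 2 rose, with the same counts adjusted over the list alone. The median log2 difference was -0.60 (camera adjusted p = 2.34e-05), with medians of -0.60 in replicates 1 and 2 and -0.59 in replicates 3 and 4. CTH, an enzyme of cysteine synthesis, fell by 1.51 ± 0.13 (SE), the serine synthesis enzyme PSAT1 by 0.96 ± 0.08 and the transcription factor DDIT3 by 0.85 ± 0.10. Myeloid markers with a kept probe rose: of 20 measured members, from 43 in the list, 11 went up and 2 down (12 and 2 adjusted over the list alone; median 0.33, adjusted p = 0.000466). They included EGR1 (also in the AP-1 and immediate early list), AIF1 of macrophages (2.61 ± 0.09), the leukocyte receptor LILRB2 (at least 2.74-fold) and the Fc receptor FCGR2B (0.62 ± 0.12). Of 25 glycolysis and hypoxia genes 9 rose and 1 fell (10 and 1 adjusted over the list alone; median 0.29, adjusted p = 0.00412). Among them were PGK1 (0.73 ± 0.09), GPI (0.52 ± 0.09) and BNIP3 (0.67 ± 0.12). Over all alternatives their limma adjusted p reached 0.0523, 0.122 and 0.156, so each missed the threshold in at least 1.

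Of 30 NF-kB targets 13 fell and 3 rose (14 and 3 adjusted over the list alone; median -0.26, adjusted p = 0.0116). In replicates 1 and 2 alone this list missed the threshold (adjusted p = 0.0698, over all alternatives 0.00102 to 0.0698). IL6 was at -0.97 ± 0.10 (SE), CCL3 at -0.92 ± 0.12, CXCL10 at -0.54 ± 0.07 and IER3 at -0.76 ± 0.12. MYC and ribosome biogenesis genes fell, 9 down and 1 up of 27 (10 and 1 adjusted over the list alone; median -0.24, adjusted p = 0.0116). The nucleolar proteins NCL, NOP58 and NOLC1 were at -0.59 ± 0.09, -0.62 ± 0.09 and -0.47 ± 0.09. MYC itself rose by 0.69 ± 0.09 (adjusted p = 0.000253). Of 34 mitosis genes 10 fell and 2 rose, the same adjusted over the list alone (median -0.21, adjusted p = 0.0116). This call was lost at adjusted p = 0.0769 with an estimated correlation (all alternatives 0.000738 to 0.0769). Genes that fell included the kinetochore motor CENPE (-0.99 ± 0.07), cyclin A (CCNA2, -0.75 ± 0.09), DLGAP5 (-0.78 ± 0.11) and CENPF (-0.77 ± 0.11). Cholesterol synthesis genes fell, 7 of 19 with none up, the same adjusted over the list alone (median -0.31, adjusted p = 0.0222). The call was lost at adjusted p = 0.0665 with an estimated correlation (all alternatives 0.00319 to 0.0665). Genes that fell included IDI1 (-0.78 ± 0.14), LSS (-0.92 ± 0.17) and the sterol sensor partner INSIG1 (-0.99 ± 0.24).

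Lysosome and phagosome genes rose, 8 up and 2 down of 25 (11 and 2 adjusted over the list alone; median 0.27, adjusted p = 0.0116). This list had adjusted p = 0.0587 with an estimated correlation, so the call was lost there (all alternatives 0.000918 to 0.0587). GLA was at 1.74 ± 0.09 (SE), TPP1 at 0.76 ± 0.11 and progranulin (GRN) at 1.09 ± 0.19. Of 26 interferon response genes 11 rose and 2 fell (12 and 3 adjusted over the list alone; median 0.19, adjusted p = 0.0222). The call was lost at adjusted p = 0.0916 with an estimated correlation and in replicates 3 and 4 alone (0.0709; all alternatives 0.00319 to 0.0916). Genes that rose included ISG20 (1.38 ± 0.16), IFI35 (0.74 ± 0.11) and IRF7 (at least 3.08-fold). Of 23 T and NK cell markers in the list only 6 had a kept probe. The 6 measured T and NK cell markers, with 4 up and none down both over all genes and adjusted over the list alone, had a median of 0.80 (adjusted p = 0.00919). The call of this list was lost at adjusted p = 0.0665 with an estimated correlation (all alternatives 0.00371 to 0.0665). The 4 that rose were CD2 (1.09 ± 0.12), the zinc finger factor BCL11B (0.78 ± 0.10), the T cell receptor zeta chain CD247 (0.81 ± 0.14) and CD4 (1.05 ± 0.34), which monocytes also express. CD4 (adjusted p = 0.044) missed the threshold without any 1 of replicates 1 and 2 of day 0 and replicates 3 and 4 of day 1, at adjusted p from 0.115 to 0.12, and also without background correction (0.0596) and with no filter on dim probes (0.0957). Over all alternatives the range was 1.71e-07 to 0.346. B cell identity genes, 7 up and 2 down of 25 and the same adjusted over the list alone (median 0.10, adjusted p = 0.0222), included IL7R and the kinase SYK (at least 4.21-fold). That call was lost at adjusted p = 0.0956 with an estimated correlation, with the replicate number (0.0952) or the set (0.106) as a block and in replicates 1 and 2 (0.104) or 3 and 4 (0.192) alone, over all alternatives 0.0115 to 0.192. The germinal centre repressor BCL6 (1.02 ± 0.07), the phosphatase PTPN6 (1.43 ± 0.14) and the B cell factor EBF1 (0.50 ± 0.09) also rose. CD79A of the B cell receptor was at 0.12 ± 0.15 (adjusted p = 0.622). IL7R, SYK and PTPN6 also act in other blood lineages.

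With an estimated correlation the calls of the integrated stress response, myeloid, glycolysis and hypoxia, NF-kB and MYC lists held on day 1. Those of the other 6 lists did not.

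The 17 lists not called on day 1 still held changed members. STAT6, an interleukin-4 signal transducer of the JAK-STAT list (5 up and 2 down of 18, adjusted p = 0.0682), rose by 1.14 ± 0.08 (SE). That list passed without replicate 3 or 4 of day 0 or replicate 1 of day 1 (0.0443, 0.0386 and 0.039), over all alternatives from 0.017 to 0.279. FOS (2.54 ± 0.17), IER2 (0.96 ± 0.14) and DUSP1 (0.50 ± 0.09) of the AP-1 and immediate early list rose, in a list with 4 up and 3 down of 18 (adjusted p = 0.13). CDKN1A, the CDK inhibitor p21, and the DNA repair factor DDB2 rose by 0.70 ± 0.11 and 0.64 ± 0.08 among the p53 targets (8 up and 4 down of 23, adjusted p = 0.312). CDK inhibitors and growth arrest genes had 2 up and 1 down of 16 (adjusted p = 0.419). Among pro-apoptotic genes (5 up and 2 down of 18, adjusted p = 0.627) BMF rose by 1.21 ± 0.19, and the death receptor FAS fell by 1.00 ± 0.17 and PMAIP1 by 0.91 ± 0.20. FKBP11, the only called member of the plasma cell list (1 up of 7, adjusted p = 0.842), rose by 1.65 ± 0.07. HLA-DOA rose by 1.19 ± 0.17 and HLA-DRA fell by 0.43 ± 0.08 among MHC class II genes (3 up and 1 down of 14, adjusted p = 0.243). In the fibroblast and epithelial list (2 up and 3 down of 5, adjusted p = 0.724) the keratin KRT8 rose at least 1.71-fold and the collagen COL1A1 fell by 0.81 ± 0.09.

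The remaining lists had adjusted p of 0.119 (replication and G1/S, 2 up and 4 down of 28), 0.0682 (MHC class I and antigen processing, 2 up of 16) and 0.777 (anti-apoptotic, 2 up and 2 down of 11). Next came 0.777 (Hodgkin cell phenotype, 6 up and 4 down of 30), 0.777 (erythroid and megakaryocytic markers, 1 up of 8) and 0.939 (cytosolic ribosomal proteins, 1 down of 43), then 0.312 (oxidative phosphorylation, 3 down of 34), 0.777 (mitochondrial ribosomal proteins, 2 up and 1 down of 32) and 0.627 (unfolded protein response, none of 17). MHC class I and antigen processing passed with the replicate number as a block (adjusted p = 0.0266) and without replicate 4 of day 0 or replicate 1 of day 1 (0.0386 and 0.0404), over all alternatives from 0.0161 to 0.196. For the pro-apoptotic, plasma cell and erythroid lists the median (-0.06, -0.19 and -0.002) was negative and the mean (0.05, 0.09 and 0.001) and the test positive. Adjusted over the list alone, counts of these 17 lists differed by at most 1 from those given, except that the 3 oxidative phosphorylation calls were lost.

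Of 10916 genes tested by limma on day 1, 2715 (24.9%) changed, 1311 up and 1404 down. At least 2-fold, 253 rose and 58 fell, against 122 and 22 with a normexp offset of 50, 367 and 124 without background correction and 385 and 125 with series matrix values. Day 1 and day 0 arrays did not overlap for 3262 genes (29.9%), where chance gives 2.86% if the sets are ignored. There were 75 genes detected on all 4 arrays of day 1 and none of day 0, and 14 the other way. As a limit, 4994 genes passed with the replicate number as a block, and 233 (187 of them at least 2-fold) when the arrays of a set were averaged to 2 values a day. With the set also as a block 4161 passed. Of the 236 named values past the threshold over the 3 comparisons, 185 also passed with averaging, and 236 with the set also as a block.

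The comparison of day 3 with day 0 asks which transcripts differ after 3 days without tetracycline. Replication and G1/S genes were lower: 23 of 28 measured members fell and none rose, the same adjusted over the list alone, with a median log2 difference of -0.997 (camera adjusted p = 1.02e-09). GINS2, a part of the replicative helicase (ILMN_1809590), fell from 10.80 ± 0.05 to 9.07 ± 0.08 (SD, n = 4; log2 difference -1.73 ± 0.07 SE, adjusted p = 7.12e-09). CDKN1A (ILMN_1784602) rose 4.33-fold from 8.91 ± 0.08 to 11.02 ± 0.18 (SD, n = 4; log2 difference 2.11 ± 0.11 SE, adjusted p = 3.25e-08). PRG2 stood 40.2-fold above day 0 at 11.71 ± 0.11 (log2 difference 5.33 ± 0.12 SE, adjusted p = 4.18e-11), and DCANP1 at least 35.6-fold. ANXA1 (ILMN_2184184) fell 9.64-fold, from 9.42 ± 0.08 to 6.15 ± 0.18 (log2 difference -3.27 ± 0.11 SE, adjusted p = 5.09e-10).

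Among the other largest rises on day 3 were ITIH1 (4.46 ± 0.12 SE), the transglutaminase TGM5 (4.17 ± 0.12, at least 17.2-fold), GPR84 (3.91 ± 0.12), TCFL5 (3.60 ± 0.14) and AIF1 (3.45 ± 0.09). The endosomal chloride transporter CLCN6 (3.40 ± 0.14) was followed by TMCC2 (3.38 ± 0.19), CFAP45 (3.31 ± 0.19) and NFXL1 (3.17 ± 0.10), with adjusted p from 1.12e-07 down to 1.72e-10. Genes detected on no array of day 0 and all 4 of day 3 included the collagen COL20A1 (at least 16.5-fold), the lectin CLEC3A (at least 13.6-fold), the dendritic cell lysosomal protein LAMP3 (at least 13.4-fold) and the zinc finger factor PLAGL1 (at least 9.21-fold). The largest falls besides ANXA1 were those of TAF9B (-3.25 ± 0.16), the nuclear pore protein TPR (-2.83 ± 0.14), autotaxin (ENPP2, -2.78 ± 0.15, at least 6.47-fold), FAM222A (at least 6.3-fold) and LRIG1 (-2.74 ± 0.10). Next were the lubricin gene PRG4 (-2.71 ± 0.08), LPXN (-2.42 ± 0.15), caldesmon (CALD1, -2.34 ± 0.11) and NLRP7 (-2.33 ± 0.10), with adjusted p from 8.13e-06 down to 3.28e-10. CCL2 fell at least 7.49-fold and was detected on no array of day 3. The same was true of the interferon-induced gene IFIT1 (at least 3.54-fold), CYP4Z1 (at least 3.51-fold), SOSTDC1 (at least 2.76-fold) and STAP1 (at least 2.60-fold). The arrays of day 3 and day 0 did not overlap for any of these genes, which the naming rule required of all but the bounds.

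Besides GINS2, the replication list held UNG, which removes uracil from DNA (-1.53 ± 0.07 SE), UHRF1, which binds hemimethylated DNA (-1.08 ± 0.07), and the helicase subunit MCM4 (-1.57 ± 0.12). Mitosis genes were not called as a list, with 9 up and 6 down of 34 (adjusted p = 0.59), a median of -0.03 and a mean of 0.04. CCNA2 (-0.97 ± 0.09), DLGAP5 (-0.58 ± 0.11), CENPF (-0.49 ± 0.11) and survivin (BIRC5, -0.46 ± 0.17) fell. CENPE and AURKA of the same list stood higher on each array of day 3 than on any of day 0. BIRC5 (adjusted p = 0.0386) missed the threshold at 0.0558 to 0.112 without any 1 of replicates 1, 2 and 4 of day 0 and 3 and 4 of day 3, and also with no filter on dim probes (0.0755) and from only the 8 arrays compared (0.0547). Over all alternatives it ran from 0.000242 to 0.239. CDK inhibitors and growth arrest genes rose, 9 up and 2 down of 16 and the same adjusted over the list alone (median 0.45, adjusted p = 0.0163). Among them were GADD45B (1.03 ± 0.08), the atypical cyclin CCNG2 (2.09 ± 0.21), the antiproliferative BTG1 (0.73 ± 0.08) and CDKN1B, the CDK inhibitor p27 (0.47 ± 0.10). p53 targets rose, 13 up and 3 down of 23, the same adjusted over the list alone (median 0.53, adjusted p = 0.00391). Among them were DDB2 (1.24 ± 0.08), the death receptor TNFRSF10B (0.94 ± 0.08) and the cytokine GDF15 (0.99 ± 0.12), which had fallen on day 1.

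Of 27 MYC and ribosome biogenesis genes 19 fell and none rose (median -0.59, adjusted p = 6.32e-05), including NOP16 (-1.13 ± 0.09 SE), MRTO4 (-1.32 ± 0.11), RRP12 (-0.79 ± 0.07) and NCL (-0.88 ± 0.09). MYC stood at 0.21 ± 0.09 (adjusted p = 0.0812). With the replicate number as a block its adjusted p was 0.0408 and without replicate 2 of day 0 it was 0.0462. It missed the threshold (0.069) when the arrays of a set were averaged and the set was a block, over all alternatives 0.0234 to 0.479. Mitochondrial ribosomal proteins fell, 21 down and 1 up of 32 (22 and 1 adjusted over the list alone; median -0.42, adjusted p = 0.000299). MRPL1 was at -1.94 ± 0.23, MRPS7 at -0.95 ± 0.14 and MRPS16 at -0.76 ± 0.11. Oxidative phosphorylation genes fell, 17 down and none up of 34 (median -0.36, adjusted p = 0.00148). NDUFA2 of complex I was at -0.90 ± 0.08, cytochrome c1 (CYC1) at -0.66 ± 0.08 and the ATP synthase gene ATP5MC1 at -1.28 ± 0.12. The other kept probe of ATP5MC1 differed by 0.56. The integrated stress response stayed low, 15 down and 2 up of 24 (median -0.68, adjusted p = 0.000589). PSAT1 was at -1.75 ± 0.08, the tryptophan tRNA ligase WARS1 at -1.07 ± 0.08, CTH at -1.50 ± 0.13 and the mitochondrial serine enzyme SHMT2 at -0.72 ± 0.07. Glycolysis and hypoxia genes rose, 14 up and none down of 25 (median 0.54, adjusted p = 5.28e-05). ANKRD37 was at 1.43 ± 0.09, BNIP3 at 1.58 ± 0.12 and the prolyl hydroxylase P4HA1 at 1.45 ± 0.11. For these lists other than the mitochondrial ribosomal one the counts adjusted over the list alone were the same. All 8 calls on day 3 held with an estimated correlation.

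Members of lists not called on day 3 went both ways. Of 14 MHC class II genes 4 fell and 2 rose (adjusted p = 0.567). The peptide exchange subunit HLA-DMB fell by 1.57 ± 0.12 (SE), the class II transactivator CIITA at least 2.93-fold, HLA-DRA by 0.67 ± 0.08 (log2) and HLA-DQB1 by 0.95 ± 0.13. HLA-DOA stood higher on each array of day 3 than on any of day 0. Among MHC class I genes (7 up and 1 down of 16, adjusted p = 0.0631) HLA-E rose by 0.71 ± 0.08 and HLA-C by 0.66 ± 0.11. This list passed with the replicate number as a block (0.0349) and without replicate 2 of day 3 (0.0481), over all alternatives from 0.0182 to 0.243. In the interferon response list (9 up and 8 down of 26, adjusted p = 0.747) IFIT2 fell by 1.58 ± 0.13, IFIT3 by 1.35 ± 0.13 and OAS1 by 1.06 ± 0.16. ISG20 and IRF7 of the same list stood higher on each array of day 3 than on any of day 0. The chaperone HSPA5 fell by 1.12 ± 0.08 and SEL1L by 1.19 ± 0.13 in the unfolded protein response list (2 up and 7 down of 17, adjusted p = 0.0631, without replicate 2 of day 3 0.0463, over all alternatives 0.00763 to 0.263). Of 30 NF-kB targets 8 rose and 6 fell (adjusted p = 0.59), with the receptor CD40 (1.36 ± 0.13), the deubiquitinase TNFAIP3 (0.93 ± 0.13) and the chemokine CCL22 (0.86 ± 0.13) up. CD40, CCL22 and the mucin MUC1 (2.63 ± 0.24) rose within the Hodgkin cell phenotype list (9 up and 7 down of 30, adjusted p = 0.59), and BATF3, an AP-1 factor, fell by 1.23 ± 0.11.

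BCL6 (1.12 ± 0.07 SE), STAT6 (0.91 ± 0.08), IL7R (at least 8.52-fold), SYK (at least 3.66-fold) and PTPN6 (2.17 ± 0.14) were higher on day 3 than on day 0. Their lists, B cell identity and JAK-STAT, had 9 up and 5 down of 25 (adjusted p = 0.112) and 6 up and 1 down of 18 (adjusted p = 0.0631). The JAK-STAT list passed without replicate 3 of day 0 or replicate 1 or 2 of day 3 (0.0486, 0.0479 and 0.0481), over all alternatives from 0.0193 to 0.263. IRF4, a factor of plasma cells and activated B cells, rose by 0.36 ± 0.10 (plasma cell list 2 up of 7, adjusted p = 0.395). IRF4 missed the threshold with median centring (adjusted p = 0.0647), with series matrix values (0.0628) and in replicates 1 and 2 alone (0.0807), over all alternatives 0.00382 to 0.115. The fetal globin genes HBG1 and HBG2 rose by 0.99 ± 0.10 and 0.96 ± 0.10 and the haemoglobin-stabilising AHSP at least 2.63-fold (erythroid list 3 up of 8, adjusted p = 0.138). LILRB2 rose at least 1.66-fold and cathepsin S (CTSS) by 0.90 ± 0.11 in the myeloid list (9 up and 4 down of 20, adjusted p = 0.0631, without replicate 3 of day 0 0.0486, over all alternatives 0.0486 to 0.207). BAD fell by 0.89 ± 0.08 and BCL2 rose by 0.63 ± 0.11 in the pro-apoptotic (6 up and 5 down of 18, adjusted p = 0.718) and anti-apoptotic (4 up and 1 down of 11, adjusted p = 0.234) lists. BCL2L11, a pro-apoptotic BH3 protein, rose by 0.50 ± 0.19 (adjusted p = 0.0451), but not when replicate 1, 2 or 4 of day 0, of day 1 or replicate 1 or 4 of day 3 was left out. Adjusted p was then 0.0529 to 0.132. It was 0.0538 without background correction, 0.0911 with no filter on dim probes, 0.0787 from only the 8 arrays compared, 0.0784 as the mean of its probes, and over all alternatives 0.0037 to 0.268. JUN (0.69 ± 0.11), CD2 (1.72 ± 0.12) and GLA (1.70 ± 0.09) rose. Their lists, AP-1, T and NK cell, and lysosome, had 3 up and 3 down of 18 (adjusted p = 0.718), 3 up of 6 (adjusted p = 0.122) and 9 up and 7 down of 25 (adjusted p = 0.457).

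The 3 lists left over on day 3 had adjusted p of 0.363 (cholesterol synthesis, 4 up and 8 down of 19), 0.495 (cytosolic ribosomal proteins, 1 up and 1 down of 43) and 0.718 (fibroblast and epithelial markers, 2 up and 2 down of 5). For mitosis (-0.03 and 0.04), pro-apoptotic (-0.09 and 0.10) and interferon response genes (-0.04 and 0.01) the median was negative and the mean, like the test, positive. Adjusted over the list alone, counts of the 20 lists not called were unchanged, except that 10 myeloid markers rose.

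In all, 5368 of 10916 genes (49.2%) changed between day 0 and day 3 by limma, 2483 up and 2885 down. At least 2-fold, 586 rose and 498 fell, against 331 and 244 with a normexp offset of 50. Without background correction these were 778 and 780, and with series matrix values 787 and 785, so that the excess of rises depends on these settings. Arrays of these days did not overlap for 4917 genes (45.0%, chance 2.86% if the sets are ignored). There were 140 genes detected on all arrays of day 3 and none of day 0, with 59 the other way. As a limit, 2418 genes passed when the arrays of a set were averaged, but 6680 when the set was also a block. With the replicate number as a block 7158 passed.

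**Figure D2:**
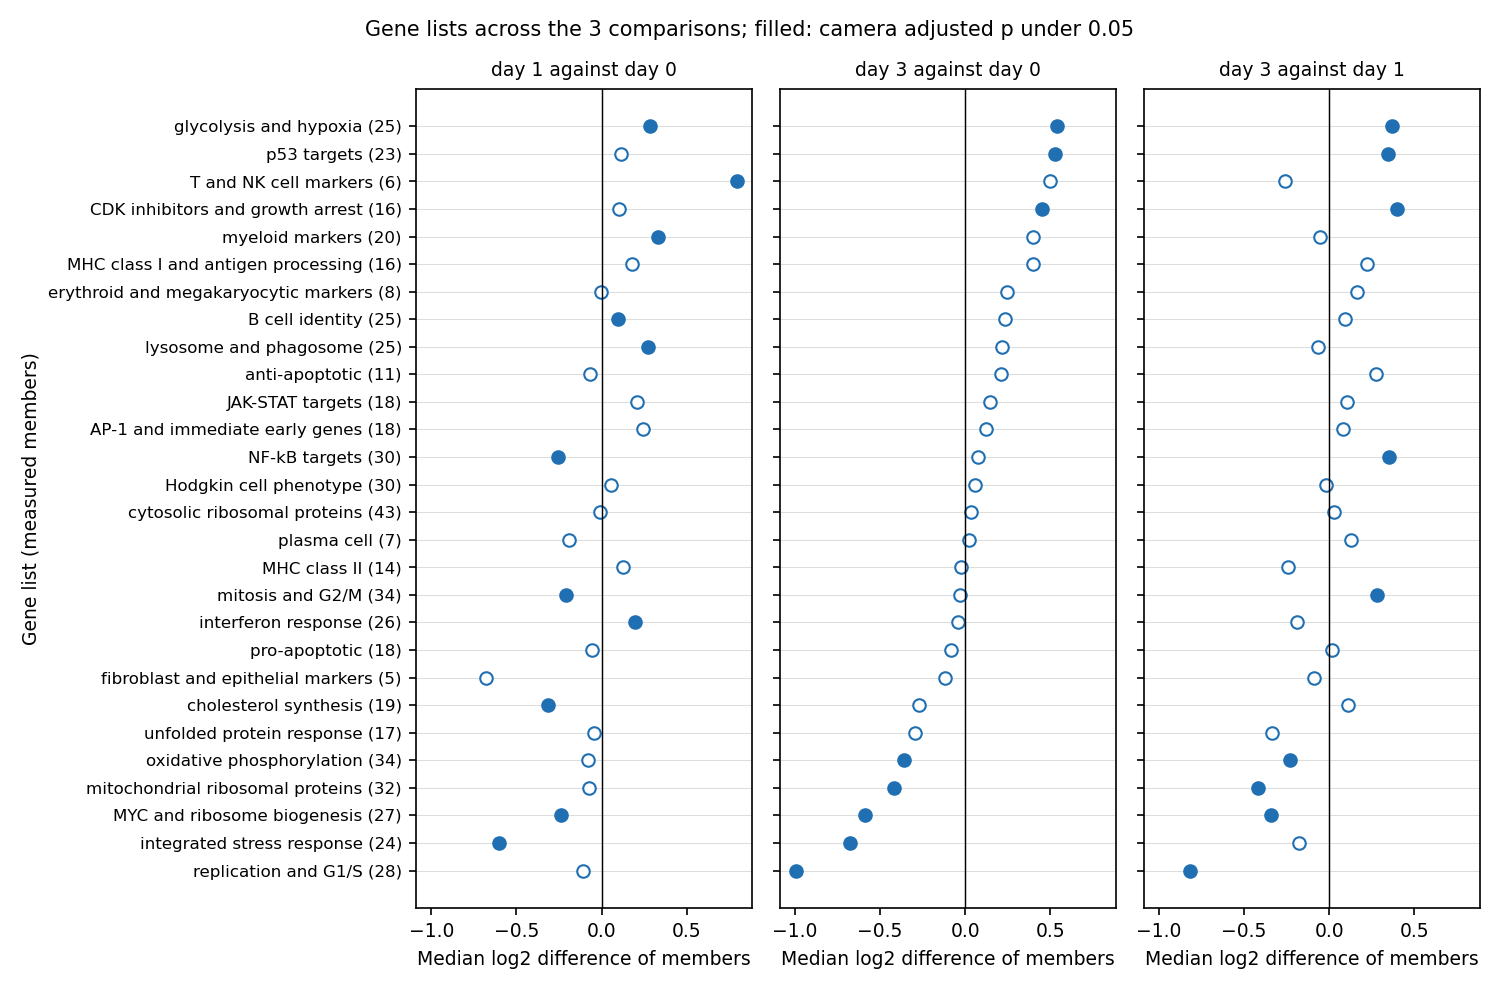
Each point is the median log2 difference of a gene list (x axis) for 1 of the 3 comparisons. Lists (y axis, measured members in parentheses) are ordered by day 3 against day 0. Filled points had a camera adjusted p under 0.05, 11, 8 and 9 lists from left to right. Replication and G1/S genes lie at -0.11, -0.997 and -0.82.

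The comparison of day 3 with day 1 asks what changed after the first day. EGR1 fell from 10.91 ± 0.21 to 7.36 ± 0.13 (SD, n = 4; log2 difference -3.54 ± 0.12 SE, adjusted p = 6.51e-09), and its log2 intensity on day 0 was 7.38 ± 0.13. FOS (ILMN_1669523) fell from 8.99 ± 0.26 to 5.56 ± 0.30 (SD, n = 4; log2 difference -3.43 ± 0.17 SE, adjusted p = 7.26e-08), against 6.45 ± 0.21 on day 0. LAMP3 (ILMN_2170814), detected on 3 arrays of day 1, rose at least 11.1-fold, from 5.32 ± 0.30 to 8.85 ± 0.11 (log2 difference 3.53 ± 0.14 SE, adjusted p = 1.38e-08). GDF15 (ILMN_2188862), detected on no array of day 1, rose at least 3.78-fold. Replication and G1/S genes fell, 22 of 28 with none up (23 and none adjusted over the list alone; median -0.82, camera adjusted p = 1.79e-11).

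Other large rises from day 1 to day 3 were those of TMEM120A (3.04 ± 0.12 SE), TGM5 (2.93 ± 0.12), CFAP45 (2.90 ± 0.19) and the proteoglycan biglycan (BGN, at least 6.01-fold). VSIG8 rose at least 5.85-fold, LY6H 5.55-fold, OTOP3 3.49-fold and C1QTNF12 3.33-fold. UBASH3B (-2.70 ± 0.24) and IL1RN (-2.39 ± 0.13) fell, and TBX2, detected on 1 array of day 3, fell at least 3.59-fold. The tetraspanin TSPAN8 fell at least 4.87-fold, TTC16 at least 3.97-fold, the lipid antigen presenter CD1C at least 3.96-fold, ZNF366 at least 3.58-fold and the serotonin transporter SLC6A4 at least 2.91-fold. Adjusted p for these 16 genes ran from 3.89e-05 down to 9.64e-09. The arrays of the days did not overlap, which the naming rule required of all but the bounds.

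GINS2 (-1.62 ± 0.07 SE), UNG (-1.47 ± 0.07), MCM4 (-1.42 ± 0.12) and UHRF1 (-1.06 ± 0.07) fell after day 1. Mitosis genes rose, 15 up and none down of 34 (15 and 2 adjusted over the list alone; median 0.28, adjusted p = 0.00458). CENPE rose by 1.66 ± 0.07, the mitotic kinases AURKA and TTK by 0.60 ± 0.10 and 0.56 ± 0.10 and HMMR by 0.97 ± 0.18. CDK inhibitors and growth arrest genes rose, 10 up and 2 down of 16 (10 and 3 adjusted over the list alone; median 0.40, adjusted p = 0.00666). CDKN1A was at 1.41 ± 0.11, GADD45B at 0.83 ± 0.08, CCNG2 at 1.57 ± 0.21 and CDKN1B at 0.44 ± 0.10. p53 targets rose, 12 up and 1 down of 23 (12 and 2 adjusted over the list alone; median 0.34, adjusted p = 0.00539), including the ribonucleotide reductase subunit RRM2B (1.39 ± 0.18). NF-kB targets rose, 12 up and 4 down of 30 (14 and 4 adjusted over the list alone; median 0.35, adjusted p = 0.00458). TNFAIP3 was at 1.22 ± 0.13, CCL22 at 1.04 ± 0.13, the adhesion molecule ICAM1 at 0.68 ± 0.10 and CD40 at 1.27 ± 0.13, whose other kept probe differed by -0.06. Glycolysis and hypoxia genes rose, 10 up and 1 down of 25 (11 and 1 adjusted over the list alone; median 0.37, adjusted p = 0.00666). ANKRD37 was at 0.97 ± 0.09, BNIP3L at 0.80 ± 0.09, P4HA1 at 0.94 ± 0.11 and BNIP3 at 0.91 ± 0.12.

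MYC and ribosome biogenesis genes fell, 12 down and 1 up of 27 (13 and 1 adjusted over the list alone; median -0.34, adjusted p = 0.00458). MRTO4 was at -1.04 ± 0.11 (SE), NOP16 at -0.70 ± 0.09 and MYC at -0.48 ± 0.09. Mitochondrial ribosomal proteins fell, 18 down and none up of 32 (median -0.42, adjusted p = 0.00018), with MRPS16 at -0.90 ± 0.11 and MRPL1 at -1.56 ± 0.23. Oxidative phosphorylation genes fell, 14 down and 1 up of 34 (median -0.23, adjusted p = 0.00488), with ATP5MC1 at -1.18 ± 0.12 and NDUFA2 at -0.76 ± 0.08. Both lists had the same counts adjusted over the list alone. All 9 calls held with an estimated correlation. The medians behind the 28 list calls of the 3 comparisons had the same sign in both sets of replicates.

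HLA-DMB fell by 1.64 ± 0.12 (SE) and CIITA at least 2.79-fold (MHC class II, 2 up and 6 down of 14, adjusted p = 0.102). IFIT1 fell at least 2.49-fold and IFIT2 by 1.2 ± 0.13 (interferon response, 4 up and 9 down of 26, adjusted p = 0.139). HSPA5 fell by 0.94 ± 0.08 (unfolded protein response, 1 up and 7 down of 17, adjusted p = 0.0839, without replicate 2 of day 3 0.0473, over all alternatives 0.0148 to 0.321). AHSP rose at least 2.64-fold (erythroid list, 3 up of 8, adjusted p = 0.0839, without replicate 2 of day 3 0.0473, over all alternatives 0.0473 to 0.238). BCL2L11 rose by 0.82 ± 0.19 (pro-apoptotic, 5 up and 4 down of 18, adjusted p = 0.932) and IRF4 by 0.56 ± 0.10 (plasma cell, 1 up and 1 down of 7, adjusted p = 0.785). EBF1 fell by 0.42 ± 0.09 (B cell identity, 3 up and 5 down of 25, adjusted p = 0.932) and BATF3 by 0.94 ± 0.11 (Hodgkin cell phenotype, 8 up and 9 down of 30, adjusted p = 0.977). Over all alternatives the limma adjusted p of BCL2L11, IRF4 and EBF1 reached 0.0856, 0.0566 and 0.11, so each missed the threshold in at least 1. The other lists had adjusted p of 0.109 (anti-apoptotic, 5 up of 11), 0.411 (MHC class I, 5 up and 2 down of 16), 0.832 (myeloid, 5 up and 5 down of 20), and 0.785 (T and NK cell, 1 up of 6). The rest had 0.837 (fibroblast and epithelial, 1 up and 1 down of 5), 0.46 (JAK-STAT, 3 up and 2 down of 18), 0.623 (AP-1, 3 up and 5 down of 18), 0.443 (cytosolic ribosomal proteins, 2 up of 43), 0.411 (integrated stress response, 4 up and 10 down of 24), 0.594 (cholesterol synthesis, 4 up and 2 down of 19) and 0.411 (lysosome, 4 up and 8 down of 25). Median and mean differed in sign for Hodgkin cell phenotype (-0.02 and 0.04), B cell identity (0.10 and -0.01) and AP-1 genes (0.08 and -0.37). The test took the sign of the mean for the first and last of these and of the median for B cell identity. Adjusted over the list alone, counts of these 19 lists differed by at most 1, except for 6 up and 7 down among myeloid markers.

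By limma 4507 of 10916 genes (41.3%) changed from day 1 to day 3, 2127 up and 2380 down. At least 2-fold, 293 rose and 314 fell, against 128 and 136 with a normexp offset of 50, 448 and 541 without background correction and 440 and 537 with series matrix values. The arrays did not overlap for 4217 genes (38.6%, chance 2.86% if the sets are ignored). There were 76 genes detected on all arrays of day 3 and none of day 1, with 56 the other way. As a limit, 1286 genes passed when the arrays of a set were averaged, but 5977 when the set was also a block. With the replicate number as a block 6555 passed.

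**Figure D3:**
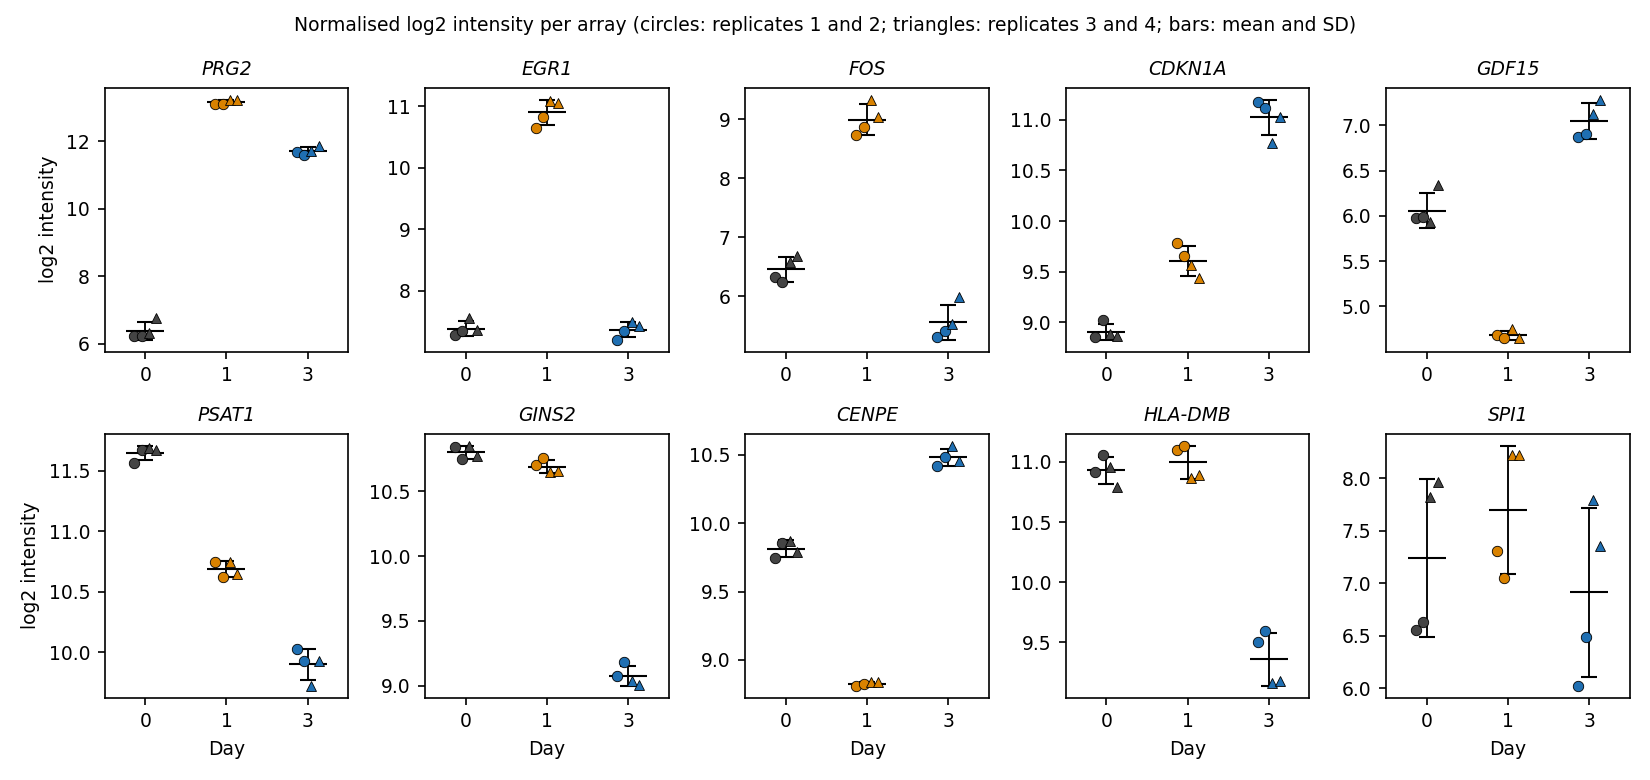
Each panel plots the log2 intensity of 1 gene (y axis, own scale) on days 0, 1 and 3 (x axis), with a point per array. Circles stand for replicates 1 and 2, triangles for replicates 3 and 4, and bars for the mean and SD of 4 arrays. EGR1 and FOS peak on day 1 (10.91 and 8.99), CENPE is lowest on day 1 (8.83), CDKN1A is highest on day 3 (11.02), and for SPI1 the sets lie apart on every day.

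SPI1 itself was measured by a pair of probes. ILMN_2392043 stood at 7.24 ± 0.75, 7.70 ± 0.61 and 6.91 ± 0.81 (SD, n = 4) on days 0, 1 and 3. The log2 differences were 0.46 ± 0.45 (SE) on day 1, -0.33 ± 0.45 on day 3 and -0.79 ± 0.45 between them, at exact two-sided permutation p of 0.4, 0.514 and 0.171, where 0.0286 is the smallest possible. Adjusted p by limma were 0.518, 0.585 and 0.189, and 0.0177, 0.0506 and 0.000597 with the replicate number as a block. Over all alternatives they ran from 0.01 to 0.793, 0.0299 to 0.967 and 0.000185 to 0.472. ILMN_1696463 differed by 0.30 ± 0.15, -0.35 ± 0.15 and -0.65 ± 0.15, at exact permutation p of 0.143, 0.0571 and 0.0286 and limma adjusted p of 0.186, 0.0701 and 0.00448 (0.0909, 0.0337 and 0.00169 with the block). For this probe the day 1 difference was 0.592 in replicates 1 and 2 and -0.00086 in replicates 3 and 4. Where these probes lie in relation to the induced copy is not known, so whether they read its expression cannot be told.

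Of the other genes fixed in advance, SPIB, a relative of SPI1, stood at -0.65 ± 0.33 (SE, adjusted p = 0.191) on day 1, -0.03 ± 0.33 on day 3 and 0.63 ± 0.33 (adjusted p = 0.161) from day 1 to day 3. With the replicate number as a block adjusted p were 0.00194 for the first and 0.00144 for the last (all alternatives 0.000864 to 0.545 and 0.000684 to 0.442). JUNB differed by 0.12 ± 0.48 on day 1 (adjusted p = 0.893), and its differences of 0.36 ± 0.48 on day 3 and 0.24 ± 0.48 from day 1 to day 3 (adjusted p = 0.574 and 0.733) passed with the block (0.00102 and 0.0132; all alternatives 0.000257 to 0.875 and 0.00567 to 1). On day 1 BATF3 stood at -0.28 ± 0.11 (adjusted p = 0.0993, with the block 0.00618, over all alternatives 0.00475 to 0.454), IRF4 at -0.20 ± 0.10, BCL2L11 at -0.32 ± 0.19, CDKN1B at 0.03 ± 0.10 and CCND2 at 0.02 ± 0.10. IRF4 passed with array weights (adjusted p = 0.0233) and in replicates 1 and 2 alone (0.0451; all alternatives 0.0233 to 0.632). BCL2L11 passed when the arrays of a set were averaged and the set was a block (0.0321; all alternatives 0.0321 to 0.642), and CD79A in replicates 1 and 2 alone (0.018; all alternatives 0.018 to 0.963). On day 3 EBF1 stood at 0.09 ± 0.09, CD79A at 0.26 ± 0.15 and CCND2 at 0.16 ± 0.10. CCND2 passed with the set as a block (0.028), but not when the arrays of a set were also averaged (0.122), and as the mean of its probes (0.00775; all alternatives 0.00775 to 0.499). CD79A passed with median centring (0.037) and in replicates 1 and 2 alone (0.0143; all alternatives 0.0143 to 0.473). From day 1 to day 3 BCL6 (0.10 ± 0.07), CD79A (0.14 ± 0.15) and CCND2 (0.14 ± 0.10) did not pass, apart from CCND2 as the mean of its probes (0.0375; all alternatives 0.0375 to 0.643). TNFRSF8 and PAX5 had probes detected on 0 arrays.

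Across genes, the day 1 and day 3 differences against day 0 had a Pearson correlation of 0.601, where unchanged groups simulated with shared day 0 arrays gave 0.499, and a covariance of 0.170 against 0.0167. Genes are not independent replicates. With the day 0 arrays split between the comparisons the correlation was 0.396 to 0.580, lowest where the split followed the sets. There were 873 genes that rose on both days (298 if independent), 859 that fell on both (371 if independent), and 90 and 91 with opposite calls. Shared day 0 arrays raise the first counts too. Of 253 genes up at least 2-fold on day 1, PRG2 and EGR1 among them, 212 were up on day 3, 93 were lower on day 3 than on day 1 and 74 higher. Of 58 down at least 2-fold, 51 were down on day 3 and 11 were higher than on day 1. Of 586 genes up and 498 down at least 2-fold on day 3, 232 and 259 were not called on day 1, which by itself does not show a difference between the days.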

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

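Tests chosen only after their result was seen are those of array brightness, of separate cultures, of tetracycline removal apart from PU.1 and of a smaller share of dividing cells.

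The sets of arrays form the first pattern: replicates 1 and 2 stood apart from replicates 3 and 4 on every day. Between the sets 6224 genes differed by limma, 2843 higher and 3381 lower in replicates 3 and 4, with 182 of these at least 2-fold, among them NACC1 (2.96 on the log2 scale), GRINA (2.20) and AGRN (1.88). A difference between probes in labelling or hybridisation, rather than in transcript level, may underlie it: over 2938 genes with 2 or more kept probes, the set difference correlated between the probes of a gene at 0.263 and the day 3 against day 0 difference at 0.811, a gap of 0.548 (95% bootstrap interval 0.494 to 0.602). Separate cultures in different states cannot be told apart from this, since 0 of 28 lists differed between sets (lowest adjusted p = 0.277). The tables argue against array brightness. In 14 comparisons on 3 days a pair of arrays from different sets was nearer in the 75th percentile of signal than a pair from 1 set of the same day, and more alike in none. The SD over genes of the log2 difference was larger between the sets by at least 0.146 (95% bootstrap interval 0.138 to 0.155).

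Integrated stress response genes were lower on day 1 than on day 0. The fall is not from one set of arrays alone, because the medians were -0.60 and -0.591 in the sets. The upper bootstrap bound for the higher, from resampling list members, was -0.377. Removal of tetracycline apart from PU.1 cannot be told apart from PU.1 here, because 0 arrays come from cells without the transgene, and PU.1 as the cause stays untested.

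Replication genes were lower on day 3 while mitosis genes as a list were not. The gap between the list medians was 0.965 (95% bootstrap interval 0.694 to 1.30). Intervals here come from resampling list members, not arrays. The gap between list means grew by 0.983 from day 0 to day 3 (exact permutation p = 0.0286, the smallest possible). That test takes the arrays as exchangeable, and the sets speak against this. Dim probes do not account for the gap between medians, which was 1.07 (0.748 to 1.41) among brighter members. Nor does one set of arrays alone, with 0.975 and 0.952. A smaller share of dividing cells, with their cycle phases unchanged, would lower both lists, and the mitosis median was -0.03244 (-0.113 to 0.201). Cycle phases were not measured, so a smaller share together with a shift of phases cannot be told apart here. Induction of PU.1, the biological explanation in the design, was not tested apart from tetracycline removal.

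Of 421 groups of 4 arrays behind the named genes, 22 had 1 array far from the others by Dixon's ratio, where chance flags about 1 in 20, here 21.05. On day 0 these were IL7R (0.842, replicate 3 low), SNAP25 (0.9, replicate 3 high), CCL2 (0.847, replicate 1 high), GDF15 (0.870, replicate 4 high), PSAT1 (0.838, replicate 1 low), IFI35 (0.923, replicate 3 high) and PTPN6 (0.832, replicate 3 high). On day 1 they were IL7R (0.894, replicate 1 low), SNAP25 (0.905, replicate 2 low), FUT9 (0.901, replicate 4 high), GPI (0.902, replicate 3 high), NOLC1 (0.855, replicate 2 high) and IER2 (0.902, replicate 2 low). On day 3 they were LRIG1 (0.890, replicate 4 low), IRF4 (0.925, replicate 3 high), CD79A (0.951, replicate 4 low), ENPP2 (0.865, replicate 1 low), NOP16 (0.850, replicate 4 high), P4HA1 (0.839, replicate 4 low), HLA-E (0.854, replicate 4 high), IFIT2 (0.911, replicate 2 high) and ZNF366 (0.836, replicate 4 low). Replicate 4 of day 3 has 6 of the 22.

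The day 1 and day 3 differences from day 0 were compared by the limma contrast of day 3 with day 1, and 27 of 41 genes named on both days differed. Lower on day 3 than on day 1 were PRG2 (-1.46 on the log2 scale), LRIG1 (-0.80), ANXA1 (-1.45), CCL2 (-1.71), SOSTDC1 (-0.48), PSAT1 (-0.79), LILRB2 (-0.73), NCL (-0.29), STAT6 (-0.23), MYC (-0.48), EBF1 (-0.42), HLA-DRA (-0.24) and BATF3 (-0.94). Higher were ITIH1 (1.03), GPR84 (0.60), DCANP1 (0.27), CYP4Z1 (0.32), GDF15 (2.36), AIF1 (0.83), BNIP3 (0.91), CD2 (0.62), PTPN6 (0.73), CDKN1A (1.41), DDB2 (0.60), CDKN1B (0.44), IRF4 (0.56) and BCL2L11 (0.82). GDF15 alone had opposite calls. The values of CCL2, SOSTDC1, CYP4Z1 and GDF15 rest on background readings. CCL2, detected on no array of day 3, fell at least 2.5-fold, and GDF15, detected on none of day 1, rose at least 3.78-fold. CYP4Z1 was detected on 0 arrays of both days and SOSTDC1 on 1 of day 1 and none of day 3, so neither has a measured change between these days. The medians of the 9 lists that differed by camera were -0.82 (replication and G1/S), 0.28 (mitosis), 0.40 (CDK inhibitors and growth arrest), 0.34 (p53 targets), 0.35 (NF-kB targets), -0.34 (MYC and ribosome biogenesis), -0.23 (oxidative phosphorylation), -0.42 (mitochondrial ribosomal proteins) and 0.37 (glycolysis and hypoxia).

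Signal also appeared outside the genes tested: 766 probes without an identifier were detected on at least 4 arrays. Of these, 88 (11.5%), 239 (31.2%) and 185 (24.2%) changed by limma in day 1 against day 0, day 3 against day 0 and day 3 against day 1. They were not assigned to genes here, and matching them by their values to the series matrix was not tried.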

How the results depend on the processing

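Tests chosen only after the sets were seen are the 6 that block, average or separate them. Of 255 gene values, at least 245 kept their direction and side of the threshold under every alternative but averaging the arrays of a set, where 51 lost their call. Averaging with the set as a fixed block leaves as few values per day. There 0 lost their call, 249 stayed the same and 6 gained one. The loss thus goes with the set difference left in the spread rather than with fewer values alone. All 28 list calls of the 3 comparisons (11, 8 and 9) kept their sign and held under each scaling, filter and variance choice and without any 1 array. With an estimated correlation 6 calls were lost, with a set as a fixed block or the replicate block 1, and in each set alone 2. Of the 56 list tests not called, 11 passed with no filter, 5 without replicate 2 of day 3 and 35 with fry. Genes changed on day 1 numbered 4994 with the replicate block, 5220 with the set as a fixed block, 4161 with averaging and that block, 1050 with the set as a random block and 233 with averaging (187 at least 2-fold). Averaging gave 2418 for day 3 against day 0 and 1286 for day 3 against day 1, and the random block 2562 for the latter. Treat, which asks for more than 1.2-fold, gave 804, 2930 and 1938. At least 2-fold changes numbered 144, 575 and 264 with an offset of 50, which shrinks differences of dim probes, 491 on day 1 and 989 between days 1 and 3 without background correction, and 510 and 977 with series matrix values. Leaving out 1 array gave 2147 to 2818, 4883 to 5367 and 3999 to 4438 changed genes. Lists numbered 5 on day 1 with an estimated correlation, and 22, 22 and 19 with fry, which does not compare a list with other genes.

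The correlation was 0.641 without background correction, 0.618 with median centring and 0.654 with series matrix values. It was 0.396 and 0.440 with day 0 arrays split by set, and 0.574, 0.575, 0.576 and 0.580 with the other splits. SPI1 passed with the replicate block at 0.46 on day 1 and -0.79 between days 1 and 3, as with a set block, with or without averaging, where day 3 (-0.33) passed too. It passed at 0.59 and -0.92 in replicates 1 and 2, at -0.65 between days 1 and 3 in replicates 3 and 4, and at -0.72 there as the mean of its probes. Besides SPI1, SPIB, BATF3, JUNB, MYC, B cell identity and MHC class I and antigen processing as reported, the replicate block changed no other call. CCL2 on day 1 lost its call without background correction (adjusted p = 0.0724) and with series matrix values (0.0576; all alternatives 7.5e-08 to 0.0724), and IRF4 on day 3 with median centring (0.0647) and series matrix values (0.0628; all alternatives 0.00382 to 0.115).

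Directions reversed only among values that missed the threshold: CDKN1B on day 1 (-0.0044 with series matrix values, -0.00043 in replicates 1 and 2, -0.0095 to 0.082 leaving out 1 array), CCND2 on day 1 (-0.026 with array weights, -0.035 in replicates 1 and 2, -0.051 to 0.068 leaving out 1), SPIB on day 3 (0.038 with array weights, 0.014 in replicates 3 and 4, -0.25 to 0.17 leaving out 1), EBF1 on day 3 (-0.059) and CD79A between days 1 and 3 (-0.043) in replicates 1 and 2, CD79A on day 1 in replicates 3 and 4 (-0.15), and, leaving out 1 array, JUNB on day 1 (-0.14 to 0.36) and between days 1 and 3 (-0.0085 to 0.50). The cause was not tested. Signal over background limits dim genes. How far counts of changed genes can be trusted depends on how the arrays of a set are alike. Of simulated data with 200 changed genes on day 1, those with a set difference shared by all days gave 1 false call (0.617% of calls), and those with the arrays of a set alike within each day gave 167 (50%). The sets here are shared by all days, since deviations of arrays of a set correlated at 0.478 to 0.697 across days. Likeness of the arrays of a set within a day beyond this was not measured directly. Averaging the arrays of a set, with the set as a block, counts such likeness in the spread. It gave 4161, 6680 and 5977 changed genes in day 1 against day 0, day 3 against day 0 and day 3 against day 1. These values argue against such likeness as the sole source of the main counts (2715, 5368 and 4507).

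Of all 35 splits of the 8 arrays of a comparison, 1 (the real one) gave as many changed genes: 2715 against at most 967 in another for day 1 against day 0, 5368 against 0 for day 3 against day 0 and 4507 against 1036 for day 3 against day 1. The same held for 2-fold counts (311 against 145, 1084 against 0 and 607 against 191) and for the 11 lists of day 1 (9). This excludes chance only if the arrays are exchangeable, and the sets speak against that: the splits giving 967, 1036, 145 and 191 follow the sets. Only 8 splits part all 4 pairs, the real one and 7 others, too few for a share under 0.05. Among these the highest other counts were 0 genes in each comparison and 9, 8 and 12 lists. On day 3, 8 lists were called, with 9 of the 35 splits as large and at most 13. Between days 1 and 3 there were 9, with 6 as large and at most 12. Every other split that called a list kept most arrays of a day together, and so carried part of the day difference. Splits with equal numbers of arrays from each day called 0 lists. For these 2 list counts the splits thus cannot decide on chance.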
